A study of Mus musculus with 36 samples.

How the data were processed

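Per the labels' protocols, each oocyte was lysed and its cDNA was made with the SMARTer Ultra Low Input kit, libraries were made with Nextera XT, and pools were sequenced in single-end mode on an Illumina HiSeq. The submitters' processing notes name STAR, featureCounts, Subread 1.5.2, Picard and the mouse genome build GRCm38, without saying which step each did. The authors deposited a table of raw counts, 21968 Ensembl genes by 36 oocytes, with whole numbers that sum to a different total in each column. The setting for strand, the treatment of reads with several matches and the annotation release are not given in the sources used here. The kits keep no strand, so reads of overlapping or antisense genes cannot be told apart. No molecular identifiers are named, and the notes do not say whether PCR copies were removed, so such copies may count as separate reads.

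Genes were named by matching their IDs to GENCODE M21 on GRCm38. Of these IDs, 21876 matched, 21714 of them protein-coding, and 3535 genes had 0 counts in every oocyte. The table holds 13 genes of the mitochondrial genome and 0 of its rRNAs, so a share restricted to protein-coding genes is the same value. It has 0 rows that name no gene.

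Samples were grouped by the genotype label and by the mouse label. Oocytes of a mouse are not independent, so counts were summed per mouse. An oocyte needed 100000 counts and 5000 genes, and all 36 passed. Each of the 306 pairs of oocytes with the same label differed by more than sampling noise (chi-square per degree of freedom of at least 5.47). Mice labelled Drp1_KO carry letters and those labelled Drp1_WT carry numbers, which name no pairs, so no pairing was used. Whether mice were matched is not known. Tube numbers 27 to 30 belong to mouse d and mouse 5 alone; they may mark a separate collection, which the labels do not say. Each title ends in a number, here called the index number, whose meaning the labels do not give. Those of the Drp1_WT libraries (up to 59) and of the Drp1_KO libraries (from 60) do not overlap.

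Changed genes were tested with edgeR 4.0.16 (R 4.3.3), with TMM factors, its filter on low counts by genotype and a robust quasi-likelihood fit, at a Benjamini-Hochberg adjusted p of 0.05. The filter left 12812 genes, and the common biological coefficient of variation was 0.214. Levels are CPM with TMM factors per mouse except for single oocytes, sums of markers and the measures compared by permutation, which use each oocyte's own total, averaged per mouse. Gene lists with at least 5 tested members were tested with camera and fry of limma 3.58.1 on log2 CPM with a prior count of 2. The 24 lists cover mitochondrial fission and fusion, the mitochondrial genome, respiratory chain subunits, ribosomal proteins of both compartments, mitochondrial DNA, the TCA cycle, fatty acids, glycolysis, 4 kinds of stress response and organelle upkeep, calcium, clearance, apoptosis, 6 parts of the oocyte programme and traffic, and 2 sets of markers of other cell types. Symbols Misato1, Filia, mt-Rnr1 and mt-Rnr2 had no match.

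Named genes followed a rule fixed before the data were examined: Dnm1l, genes past the threshold by size of change, the 10 smallest p where fewer than 5 genes pass, and up to 4 members with the smallest p in each list. Other genes near Mfhas1, Naip1, Nyap2 and genes described in tube 10 of mouse b were named after their values were seen. Detected genes, the mitochondrial share, the share of the 50 most abundant genes, totals, Dnm1l and the dissimilarity of oocytes of a mouse were compared as mouse means with an exact two-sided permutation test over all splits of the mice (scipy 1.17.1), adjusted over these 6 measures. Dissimilarity was 1 minus Spearman's correlation of log2(CPM+1) with oocytes thinned to 3178509 counts. Intervals of shares cover counting error only.

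Alternatives fixed before the data were examined were DESeq2 1.42.0, other scaling factors, other filters on genes and oocytes, limma-voom on oocytes with mouse as a random effect, limma-trend on mean log2 CPM, thinning, removal of the mitochondrial genome, the tube set left out or as a term, and each mouse left out. Alternatives without KO tube 10, WT tubes 11 to 15 and WT tube 29, and with limma's cameraPR on edgeR statistics, as such and with their trend on gene length removed, were added after seeing the data. Lists were also tested with cameraPR under voom.

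The scripts were tested on simulated data with the real means and library sizes, in the comparison of 4 against 5 mice. Over the 12656 genes run, edgeR recovered 25.4% of 67 genes changed 1.5-fold, 89.6% of 67 changed 2-fold and 100% of 66 changed 4-fold, all of at least 10 CPM, with 7 false calls among 152. DESeq2 made 30 false calls among 191, and voom with mouse as a random effect, over 12812 genes, 13 among 176. A simulated list of 74 genes raised by 0.3 on the log2 scale had an adjusted p of 3.31e-14 with camera's preset correlation, 0.000371 with an estimated correlation and 7.33e-05 with fry of limma. Of the 23 other lists, left as they were, camera called 0 in either form and fry called 1. The simulated mouse effect was drawn for each gene on its own, with no tube set, so list members did not covary among mice. The 4 real lists called below had estimated correlations of 0.392 to 0.915. The simulated list results thus do not give the power or the false calls for the real lists. The simulation also held more changed genes than were called in the real data, which loosens the adjusted threshold, and no library like KO tube 10. The shares of genes recovered thus do not give the power or the false calls for the real genes either.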

Results

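Fully grown oocytes at the germinal vesicle stage, arrested in prophase of the first meiotic division, were sequenced as 36 single-cell libraries. The labels assign 18 oocytes from 4 mice (a to d) to Drp1_KO and 18 oocytes from 5 mice (1 to 5) to Drp1_WT. Drp1, the product of Dnm1l, is the dynamin-related GTPase that divides mitochondria. Totals ran from 3178509 to 7406895 counts per oocyte, with 11350 to 14659 genes detected. Each mouse contributed 3 to 5 oocytes, and the mouse was the replicate throughout, with n = 4 for the libraries labelled Drp1_KO and n = 5 for those labelled Drp1_WT. Tube numbers in the titles ran from 1 to 15 for most mice, and from 27 to 30 for mouse d and mouse 5.

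Dnm1l (ENSMUSG00000022789, chromosome 16, 16312230 to 16358959, GRCm38) was examined first, since it checks the labels. Its normalised level was 207 ± 15.8 CPM (SD, n = 4) in mice labelled Drp1_KO and 239 ± 69.2 CPM (SD, n = 5) in mice labelled Drp1_WT. The log2 fold change was -0.21 (SE 0.19), and edgeR's quasi-likelihood test gave an adjusted p of 0.706. An exact two-sided permutation test of the mouse means of log2(CPM+1) over all splits of the 9 mice gave p = 0.413, with a difference of -0.22. Within tubes 1 to 15 that difference was -0.07 (exact permutation p = 1, 3 against 4 mice), while tubes 27 to 30 hold 1 mouse of each label, at 165 CPM per oocyte in mouse d and 278 CPM in mouse 5.

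The mice labelled Drp1_WT did not share a common Dnm1l level. Single oocytes of the Drp1_KO label ranged from 144 to 274 CPM. Among libraries labelled Drp1_WT, 13 lay between 234 and 322 CPM and the other 5, in tubes 11 to 15, lay between 116 and 156 CPM. The latter are 2 oocytes of mouse 3 and all 3 oocytes of mouse 4, and 17 of the 18 libraries labelled Drp1_KO had more Dnm1l than the highest of them. Dnm1l thus goes against the label in these 5 libraries, and each direction below is drawn from the labels as given. The counts cover the whole gene, the labels do not name the deleted part, and reads from exons outside it would still count.

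**Figure D1:**
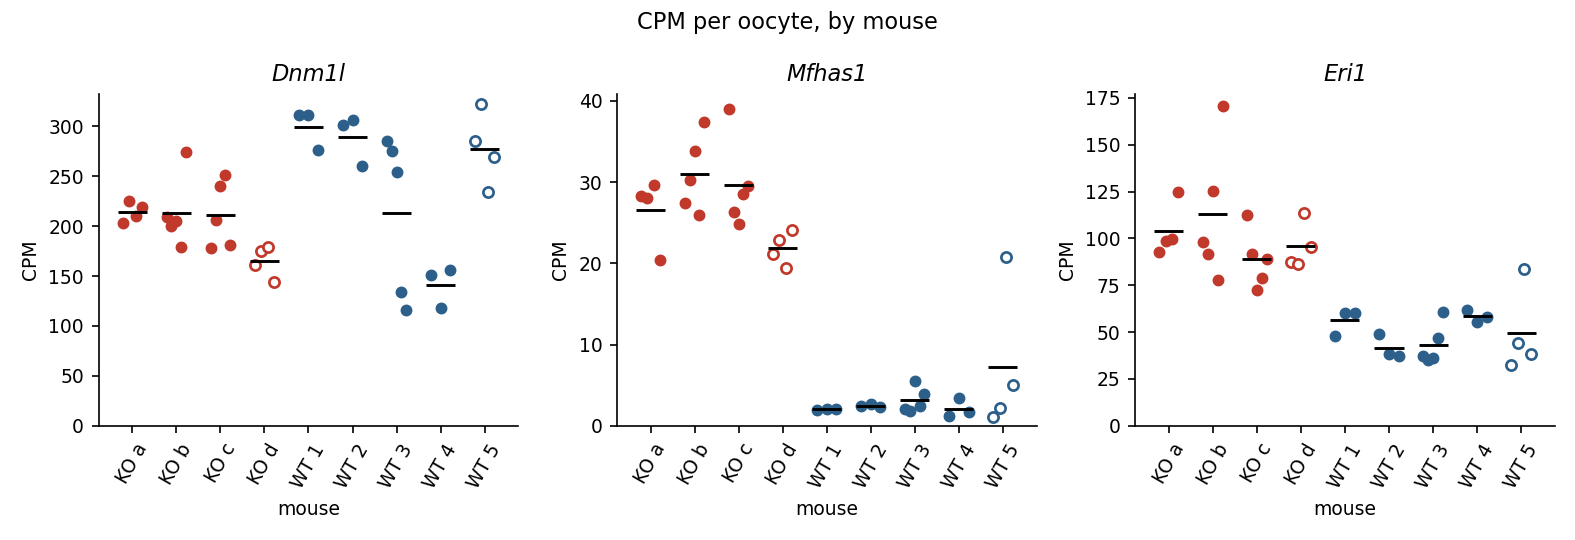
CPM per oocyte of Dnm1l, Mfhas1 and Eri1 (y axes) by mouse (x axis), red for the label Drp1_KO and blue for Drp1_WT, with open symbols for tubes 27 to 30 and black bars for the mean of the oocytes of each mouse. Dnm1l of 5 oocytes in mice 3 and 4 lay between 116 and 156 CPM, while Mfhas1 was at least 19.4 CPM in every library labelled Drp1_KO and at most 5.47 CPM in libraries labelled Drp1_WT other than tube 29 of mouse 5, at 20.8 CPM.

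Comparing the labels across the transcriptome asks which transcripts differ between oocytes labelled Drp1_KO and Drp1_WT. Mfhas1 and Eri1 were higher in libraries labelled Drp1_KO. Mfhas1 (ENSMUSG00000070056), which encodes a leucine-rich repeat protein of the ROCO family, stood at 28 ± 3.02 CPM (SD, n = 4) against 3.33 ± 2.20 CPM (SD, n = 5), an 8.27-fold difference (log2 3.05, SE 0.32, adjusted p = 0.00389 by edgeR). Eri1 (ENSMUSG00000031527), an exoribonuclease that acts on the ends of histone mRNA, stood at 102 ± 12.8 against 48.6 ± 7.09 CPM, a 2.10-fold difference (log2 1.07, SE 0.13, adjusted p = 0.0118 by edgeR). Every Drp1_KO mouse lay above every Drp1_WT mouse for both genes. They were the 2 genes past an adjusted p of 0.05 among 12812 tested, with 0 lower, and 1242 genes had an unadjusted p under 0.05.

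Mfhas1 and Eri1 are neighbours on chromosome 8. Eri1 spans 35465253 to 35496196 on the minus strand and Mfhas1 spans 35587798 to 35679449 on the plus strand, 91601 bases apart. Of 5 other tested genes within 1 Mb of the pair, Gm19410 had the smallest unadjusted p (0.0830, log2 0.25, SE 0.13, adjusted p = 0.537 by edgeR), and Tnks, Lonrf1, Trmt9b and Dlc1 had larger ones. Tube 29 of mouse 5, labelled Drp1_WT, held 20.8 CPM of Mfhas1 and 83.7 CPM of Eri1, within the range of the libraries labelled Drp1_KO, where the lowest values were 19.4 and 72.4 CPM. The 5 libraries labelled Drp1_WT with little Dnm1l held 1.27 to 3.88 CPM of Mfhas1. DESeq2 called 39 genes (15 higher, 24 lower) and limma-voom on single oocytes called 10 (7 higher, 3 lower), each set with Mfhas1 and Eri1 in it. Without mouse a, b, 2 or 3 in turn, edgeR's adjusted p of Eri1 became 0.0784, 0.0850, 0.0566 and 0.0589, with a log2 fold change of 1.07, 1.01, 1.01 and 1.02, while Mfhas1 passed each time.

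**Figure D2:**
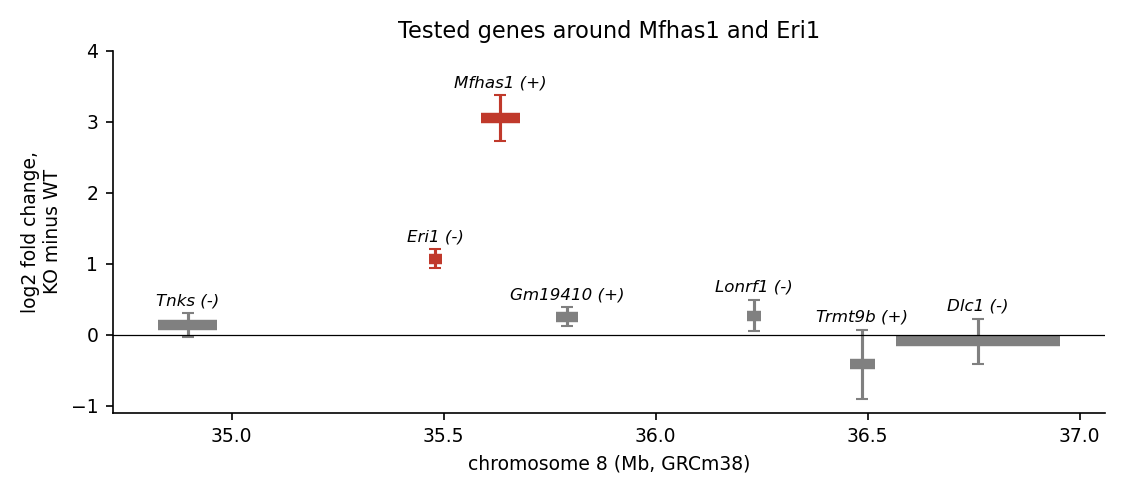
Log2 fold change of the libraries labelled Drp1_KO against Drp1_WT (y axis, error bars 1 SE) of tested genes around Mfhas1 and Eri1, drawn over their spans on chromosome 8 (x axis, Mb, GRCm38) with their strand in brackets. Mfhas1 (3.05) and Eri1 (1.07) in red passed the threshold, and the 5 other genes in grey did not.

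The next 8 genes by p did not pass the threshold, with edgeR adjusted p of up to 0.314. DESeq2 called all 8 and limma-voom called Nif3l1, Gulo and Dip2c. Nif3l1 stood at 74.8 ± 3.6 against 49 ± 4.47 CPM and Mctp1, a C2-domain calcium-binding protein, at 31.7 ± 3.69 against 20.1 ± 2.15 CPM (KO against WT labels, SD, n = 4 and 5). Trip10, an F-BAR adaptor of the cytoskeleton, stood at 15.4 ± 1.22 against 24.3 ± 0.80 CPM, and Plek, pleckstrin, at 7.54 ± 1.02 against 16.2 ± 4.59 CPM. Gulo, the last enzyme of vitamin C synthesis, stood at 11.7 ± 1.18 against 21.1 ± 3.74 CPM, Dip2c at 10.9 ± 2.21 against 20.01 ± 2.80 CPM, and Dpp9, a dipeptidyl peptidase, at 1.74 ± 0.287 against 3.63 ± 0.458 CPM. Chrdl1, a secreted antagonist of BMP ligands, was counted in 9 of 18 libraries labelled Drp1_WT, at up to 12.5 CPM, and in 2 of 18 labelled Drp1_KO, at up to 0.337 CPM.

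Of 24 gene lists fixed before the data were examined, 4 lay higher in libraries labelled Drp1_KO by limma's camera test with a preset correlation of 0.01. These were the genes of the mitochondrial genome (9 tested, median log2 1.13, adjusted p = 1.1e-04), mitochondrial ribosomal proteins (77 tested, 0.12, adjusted p = 0.00483), cytosolic ribosomal proteins (80 tested, 0.09, adjusted p = 0.0149) and nuclear-encoded respiratory chain subunits (78 tested, 0.11, adjusted p = 0.0248). With an estimated correlation, limma's camera gave each of the 4 an adjusted p = 0.961, and limma's fry gave an adjusted p = 0.912. The 3 lists of nuclear genes did not pass camera without mouse d, 1 or 4 (adjusted p 0.185 to 0.892), with camera's direction for cytosolic ribosomal proteins and the respiratory chain turned down without mouse d, and the respiratory chain list did not pass without mouse 3 (adjusted p = 0.0684). The lists covaried among mice of both labels: cytosolic ribosomal proteins had a mean centred log2 CPM of 0.42 in mouse d and 0.29 in mouse 5, both from tubes 27 to 30, against -0.34 in mouse 1 and -0.31 in mouse 4. Without WT tubes 11 to 15, a choice made after seeing the data, camera with the preset correlation called the mitochondrial genome alone, and without these, KO tube 10 and WT tube 29 it called 0 lists; in both cases the direction of the same 2 lists was down.

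The mitochondrial genome's transcripts were most abundant in a single library, tube 10 of mouse b. All 9 tested had a positive fold change and 8 had an unadjusted p under 0.05, but 0 passed over all genes by edgeR, DESeq2 or limma-voom. Adjusted over the list alone 5 were higher, and without tube 10 this became 0, while camera with the preset correlation still called the list (adjusted p = 0.00721 by limma). With all libraries, limma's camera gave this list an adjusted p = 0.961 with an estimated correlation. Examples are mt-Nd1, at 1122 ± 1025 against 376 ± 173 CPM, mt-Nd2, at 580.0 ± 603 against 181 ± 66.8 CPM, and mt-Nd3, at 14.9 ± 15.5 against 5.05 ± 1.3 CPM (SD, n = 4 and 5). Mouse b held 2644 CPM of mt-Nd1, the other mice labelled Drp1_KO 413 to 725 CPM. In tube 10 the mitochondrial genome took 5.61% of counts (95.0% Wilson interval 5.59% to 5.63%, for counting error only), against 0.140% to 0.669% in all other libraries. By mouse the share was 0.591% ± 0.526 in mice labelled Drp1_KO and 0.284% ± 0.0817 in those labelled Drp1_WT (exact two-sided permutation p = 0.222, n = 4 and 5), and without tube 10 the first was 0.326% ± 0.0512 (exact permutation p = 0.429).

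Among 235 tested ribosomal and respiratory chain genes, 0 passed over all genes by edgeR, DESeq2 or limma-voom, or adjusted over the list alone, and 4 had an unadjusted edgeR p under 0.05, all higher in libraries labelled Drp1_KO. Mrpl15 stood at 63.1 ± 2.44 against 48.4 ± 7.22 CPM and Mrps10 at 14.1 ± 1.29 against 10.0 ± 2.39 CPM. Rps15a stood at 44.6 ± 16.5 against 29.8 ± 6.83 CPM, Rps27l at 354 ± 132 against 252 ± 70.4 CPM and Cox7a2l at 299 ± 46 against 255 ± 47.5 CPM (KO against WT labels, SD, n = 4 and 5).

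**Figure D3:**
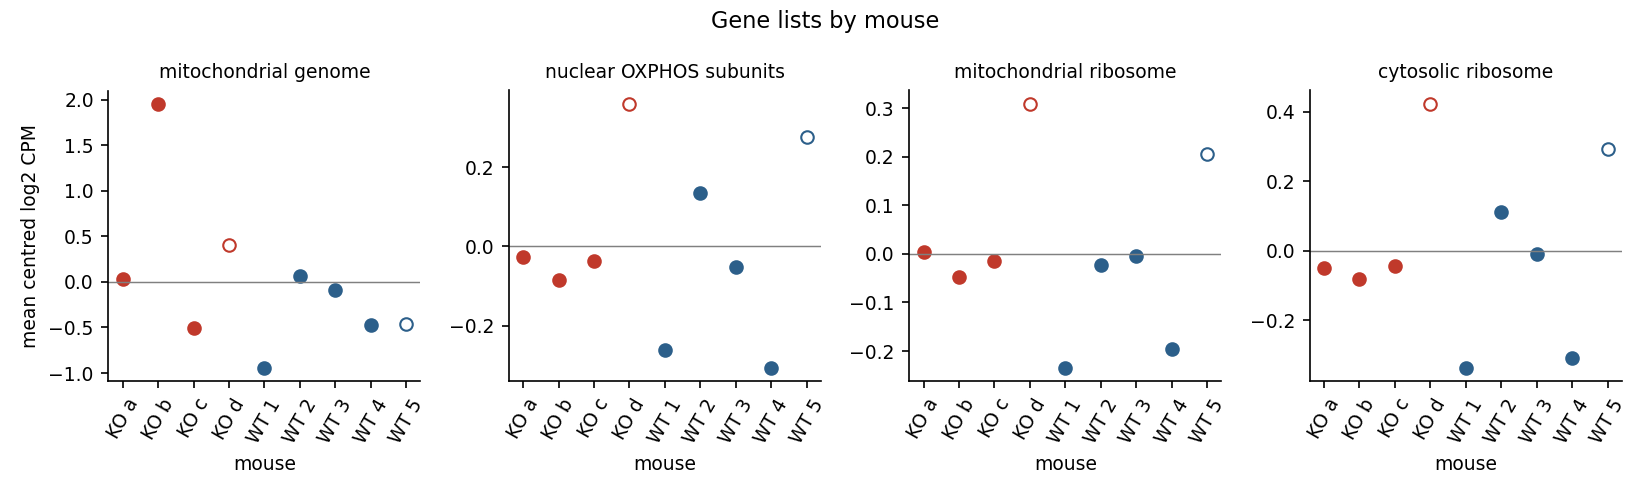
Mean over the members of 4 gene lists of the log2 CPM centred on the 9 mice (y axis, scales differ) by mouse (x axis), red for the label Drp1_KO and blue for Drp1_WT, open for the mice of tubes 27 to 30. Mouse b stood at 1.96 for the mitochondrial genome, while mouse d and mouse 5 were highest for cytosolic ribosomal proteins at 0.42 and 0.29.

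The other 20 lists did not pass, with adjusted p from limma's camera between 0.220 and 0.959, between 0.961 and 0.968 with an estimated correlation, and between 0.912 and 0.991 by fry. Mitochondrial fission and fusion genes without Dnm1l (26 tested, median log2 -0.00) included Chchd3 at 113 ± 6.90 against 96.2 ± 8.54 CPM and Dnm2 at 24.7 ± 7.35 against 33.4 ± 12.3 CPM. Regulators of mitochondrial DNA (24 tested, median -0.05) included Polrmt, the mitochondrial RNA polymerase, at 42.9 ± 11.6 against 57.9 ± 5.48 CPM, and Twnk, its helicase, at 13.5 ± 2.72 against 18.8 ± 4.89 CPM. Pyruvate oxidation and the TCA cycle (29 tested) had a median of 0.02 but a mean of -0.04, with camera's direction up. Medians were -0.04 for fatty acid oxidation and lipid droplets (30 tested) and -0.15 for glycolysis and the pentose pathway (24 tested). In the former, Dgat1 stood at 2.92 ± 0.488 against 5.14 ± 1.16 CPM and Acadm at 116 ± 29.4 against 81.0 ± 22.3 CPM. That list had 2 members higher and 4 lower at an unadjusted edgeR p under 0.05. Of the 133 members tested, 0 passed over all genes by edgeR, DESeq2 or limma-voom, or adjusted over the list alone, with 4 higher and 8 lower at an unadjusted edgeR p under 0.05.

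Among 184 tested stress and clearance genes, 0 passed over all genes by edgeR, DESeq2 or limma-voom, or adjusted over the list alone, with 4 higher and 6 lower at an unadjusted edgeR p under 0.05. The integrated stress response (32 tested, median -0.09, adjusted p = 0.220 by limma's camera) included Stc2 at 2.39 ± 0.658 against 4.67 ± 1.64 CPM and Aars at 26.2 ± 5.10 against 35.9 ± 7.77 CPM. Medians were -0.05 for mitochondrial chaperones and proteases (22 tested, Clpx 43.6 ± 3.12 against 54.6 ± 8.57 CPM), -0.09 for the endoplasmic reticulum stress response (26 tested), 0.07 for calcium stores and contacts (26 tested), -0.07 for mitophagy and autophagy (25 tested) and 0.09 for apoptosis and p53 targets (25 tested). Antioxidant enzymes (29 tested) had a median of -0.03 while camera's direction was up.

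Genes that mark the oocyte's own programme showed 1 member past the threshold adjusted over the list alone. This was Spire2, an actin nucleator of spindle positioning, at 6.36 ± 0.877 against 11 ± 2.06 CPM (list-adjusted p = 0.0335, over all genes 0.398, by edgeR), and DESeq2 called it over all genes. Of the 200 distinct genes tested in these lists, edgeR called 0 over all genes and limma-voom 0, DESeq2 called Spire2 and Kdm5b, and 14 higher and 10 lower had an unadjusted edgeR p under 0.05. The other members of the meiosis and cell cycle list (47 tested, median -0.02, camera's direction up) included Mad2l1 at 962 ± 262 against 698 ± 108 CPM. Maternal-effect genes (38 tested, median -0.05) included Dnmt3a at 80.2 ± 13.5 against 111 ± 22.7 CPM and Tle6, of the subcortical maternal complex, at 1606 ± 415 against 2238 ± 547 CPM. Zona pellucida, secreted and transcription factors of the oocyte (29 tested, median 0.02) included Zp1 at 773 ± 163 against 1035 ± 90.6 CPM. All means of mice labelled Drp1_KO given here contain tube 10 of mouse b, where Zp1 stood at 13.5 CPM. In that library 24 of 38 maternal-effect genes lay below every other library and 5 above. Of 37 genes of maternal RNA storage and decay, 18 lay above and 12 below. Medians were 0.01 for maternal RNA storage and decay (35 tested, Btg4 5083 ± 1192 against 4003 ± 267 CPM), -0.01 for DNA and histone modifiers (33 tested, mean 0.04, camera's direction up, Kdm5b 13.9 ± 1.56 against 9.20 ± 1.34 CPM) and 0.00 for the secretory pathway (26 tested, mean -0.02, camera's direction up).

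Markers of other cell types did not differ past the threshold over all genes, and those of immune cells stood out in tube 10 of mouse b. Granulosa and cumulus markers (16 tested, median -0.25) included Cyp11a1 at 1.4 ± 0.602 against 4.63 ± 3.75 CPM, Cyp19a1, the aromatase, at 67.4 ± 6.79 against 57.1 ± 5.33 CPM and Hsd3b1 at 2.31 ± 0.807 against 5.79 ± 5.44 CPM, and 0 passed either threshold, with 1 of them, lower, at an unadjusted edgeR p under 0.05. Their summed level was 143 ± 10.6 against 149 ± 16.7 CPM (exact two-sided permutation p = 0.556, n = 4 and 5). Of 6 tested markers of stroma, endothelium, epithelium and immune cells (median -0.46), Cd68 was higher and Krt8 and Kdr were lower adjusted over the list alone, and 0 passed over all genes by edgeR, DESeq2 or limma-voom. The summed level of this set was 72.3 ± 53.8 against 50.2 ± 8.17 CPM (exact two-sided permutation p = 0.651, n = 4 and 5), with 572 CPM in tube 10 and at most 76.7 CPM in any other library, and without tube 10 the first mean was 46 CPM (exact permutation p = 0.524). Without tube 10 of mouse b the same 3 genes passed over the list alone. Cd68, a macrophage lysosomal protein, stood at 8.07 ± 5.51 against 3.08 ± 0.940 CPM, and reached 67.8 CPM in tube 10 of mouse b and at most 7.56 CPM in the other 35 libraries.

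Fewer genes were detected in oocytes labelled Drp1_KO. The mean per mouse was 13596 ± 161 (SD, n = 4) against 14013 ± 73 (SD, n = 5), a difference of -417 genes or -2.97%, and every mouse labelled Drp1_KO lay below every mouse labelled Drp1_WT. The exact two-sided permutation p was 0.0159, the smallest that the splits of 9 mice allow, and 0.0952 with Benjamini-Hochberg adjustment over 6 measures, which does not pass. With oocytes thinned to the same total the difference was -321 genes (exact permutation p = 0.0159). Within tubes 1 to 15 it was -385 genes (exact permutation p = 0.0571, the smallest that 3 against 4 mice allow), and tubes 27 to 30 hold 1 mouse of each label, at 13435 and 13924 genes. Total counts per oocyte were 5692378.5 ± 312807 against 6058623 ± 303416 (exact permutation p = 0.0794), and the 50 most abundant genes took 20.1% ± 1.65 against 18.7% ± 0.552 of counts (exact permutation p = 0.127). Leaving out libraries was a choice made after seeing the data. Without KO tube 10 the difference in detected genes was -283 (exact permutation p = 0.0476). The labels then overlapped, with up to 14018 genes in mice labelled Drp1_KO and at least 13924 in those labelled Drp1_WT. Without WT tubes 11 to 15 and 29 and KO tube 10, the difference was -210 (exact permutation p = 0.143, 4 against 4 mice).

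Oocytes of the same mouse differed by 0.0523 ± 0.0395 (1 minus Spearman's correlation, SD, n = 4) under the Drp1_KO label and by 0.0363 ± 0.00696 (SD, n = 5) under the Drp1_WT label (exact two-sided permutation p = 0.714). Mouse b stood at 0.111 and the other mice labelled Drp1_KO between 0.0297 and 0.0365. Without tube 10 of mouse b the order of the group means turned, to 0.0322 ± 0.00295 under the Drp1_KO label (exact permutation p = 0.302).

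**Figure D4:**
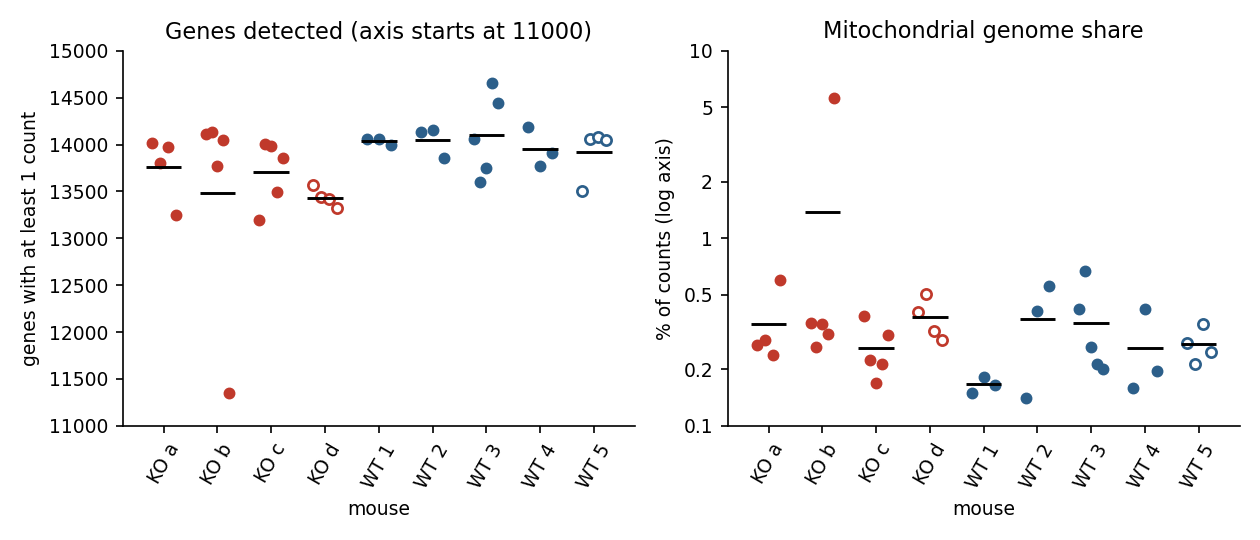
Genes with at least 1 count (left, axis not from 0) and the mitochondrial genome's share of counts in percent (right, log axis) per oocyte, by mouse (x axis), red for the label Drp1_KO and blue for Drp1_WT, open for tubes 27 to 30, with black bars for the mean of the oocytes of each mouse. Tube 10 of mouse b had 11350 genes and a share of 5.61%, and the other libraries 13199 to 14659 genes and 0.140% to 0.669%.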

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

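The values here stood apart from the other mice of their label by a gap test at the 95% level, which by chance picks about 1 in 20 groups. It picked 16 of 222 groups of mice, and the values are given as measured. Leaving out tube 10 was chosen after the data were seen.

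In mouse b, labelled Drp1_KO, the mitochondrial genome's share of counts was 1.38% (0.259% to 0.380% in the other mice of the label), the dissimilarity among its oocytes 0.111, mt-Nd1 2644 CPM, mt-Nd2 1478 CPM, mt-Nd3 37.9 CPM and Gdap1 221 CPM. These values contain tube 10, and without it the mean share of the mice labelled Drp1_KO was 0.326%. In mouse d, also labelled Drp1_KO and from tubes 27 to 30, Ndufab1 stood at 84.4 CPM and Cycs at 43.9 CPM, above the other mice of the label, and Trp73 at 14.1 CPM, below them.

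In mouse 5, labelled Drp1_WT and from tubes 27 to 30, Mfhas1 stood at 7.19 CPM (1.99 to 2.99 CPM in the other mice of the label), Dcn at 7.19 CPM (1.31 to 1.45 CPM), Chchd3 at 111 CPM and total counts per oocyte at 6590337. The Mfhas1 value contains tube 29, at 20.8 CPM, while the other 3 oocytes of mouse 5 held 1.08 to 5.00 CPM. In mouse 2, Plek was high at 24.2 CPM and Cnot7 low at 484 CPM. In mouse 1, Rps15a was low at 18.2 CPM.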

How the results depend on the processing

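Libraries in doubt (WT tubes 11 to 15 for their low Dnm1l, WT tube 29 for Mfhas1 and Eri1 at the level of the Drp1_KO label, KO tube 10 for its few genes) were left out, and cameraPR and the removal of the length trend were added, only after seeing the data. The 2 called genes became 39 with DESeq2, 10 with voom on oocytes and 4 without tubes 27 to 30 (Mfhas1, Eri1, Naip1 and Nyap2), and 1 to 3 when a mouse was left out; the cause was not tested. Mfhas1 and Eri1 were both called in 14 other alternatives with 2 calls. Of these, the fit with no oocyte filter equals the main fit, since all 36 oocytes passed. It adds nothing here or in the values of named genes below. The 4 lists past the threshold became 2 without tubes 27 to 30; 1 with a mean of at least 10 CPM, voom with cameraPR, limma-trend or without WT tubes 11 to 15; 0 with an estimated correlation, fry or without all libraries in doubt; and 1 to 5 when a mouse was left out, the added one without mouse b being the integrated stress response, lower (limma adjusted p = 0.0443). With cameraPR on edgeR statistics 3 passed, and 1 with their length trend also removed. Thinning to equal totals left 3, with cytosolic ribosomal proteins at a limma adjusted p = 0.0715. Genes detected differed by -385 without tubes 27 to 30 (exact permutation p = 0.0571, where fewer mice allow no smaller p), by -210 without all libraries in doubt (exact permutation p = 0.143), and by -472 to -363 when a mouse was left out. Dissimilarity turned to -0.00479 without oocytes low in detected genes, to -0.00407 without KO tube 10 and to -0.0029 without all libraries in doubt, and ranged from -0.00371 to 0.0235 when a mouse was left out, since each reversal leaves out tube 10 or mouse b. The Dnm1l fold change stayed negative, from -0.53 to -0.08 (edgeR, DESeq2 or limma adjusted p 0.298 to 0.921); its largest value, without libraries chosen for their Dnm1l, is not a test. The difference in mitochondrial share stayed positive, from 0.0186 to 0.418 percentage points. Over 105 other named genes, 2670 of 2690 values kept direction and side of the threshold. Only Mfhas1 and Eri1 of them passed in the main fit, so for the rest this mostly means staying short of the threshold. Most were also chosen by the smallest p of their list, which favours a steady direction. The log2 fold change of Rps27l turned to -0.054 without all libraries in doubt, and the Dcn log2 fold change ranged from -0.908 to 0.17 when a mouse was left out, the latter without mouse 5; the cause was not tested. With oocytes thinned to the same total, 11941 in place of 12812 genes passed the filter on low counts, so depth limits which of them could be tested.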

Other observations

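The tests of explanations here were chosen after the results were seen, except that thinning to equal totals and the tube set as a term were alternatives fixed earlier. Tube 10 of mouse b, labelled Drp1_KO, differed from the other 35 libraries in many transcripts. Lyz2, the lysozyme of macrophages and other myeloid cells, stood at 440.0 CPM (2153 counts) against at most 0.852 CPM elsewhere, Cd52 at 31.9 against at most 0.179 CPM, C1qa, a complement component made by macrophages, at 17.2 against at most 0.161 CPM, and Cd68 at 67.8 against at most 7.56 CPM. Ptprc, the leukocyte common antigen, had 6 counts. Col1a1, Col3a1, Hbb-bs and Krt8 had 0 counts there, but the first 3 were at most 0.682 CPM in any other library, so their 0 counts say little. Pecam1, also of this set, had 54 counts. Of 26 granulosa and cumulus markers, 5 were higher in tube 10 than in any other library and 0 lower, with Gja1 at 20.2 against at most 13.5 CPM. All 13 mitochondrial genome genes were higher there than in any other library, while 70 of 82 cytosolic ribosomal, 64 of 78 mitochondrial ribosomal and 64 of 78 respiratory chain genes were lower than in any other library. Among 30 zona, secreted and transcription factors of the oocyte, 18 were lower there than in any other library and 6 were higher. Zp3, a zona pellucida protein, stood at 13.5 CPM and Gdf9, an oocyte growth factor, at 125.7 CPM, while Rfpl4 stood at 13139 against at most 3649 CPM elsewhere.

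The count of 2 called genes by edgeR was equalled or passed in 3 of 100 splits of the mice, the real one included. This share was not adjusted for the 4 counts compared over these splits, and 2 other splits gave more calls, so it does not exclude chance. The highest other split gave 9, with mice d, 2, 3 and 5 against the rest, and another gave 4, with a, b, d and 5; both put the mice of tubes 27 to 30 on the same side. With the tube set as a term in edgeR, the count was 2. Chance is also not excluded for DESeq2's 39 calls, reached in 11 of 100 splits (highest other 1342). The same holds for the 1242 genes with an unadjusted edgeR p under 0.05, reached in 18 (highest other 3175). It holds for the 4 lists too, reached in 61 (highest other 10). Splits with many times the real count point to a structure of the samples. Of the other splits that reach the real count, those with the mice of tubes 27 to 30 on the same side are 9 of 10 for DESeq2 and 16 of 17 for the unadjusted p, against 44 of all 100. For the lists they are 40 of 60, a smaller excess.

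Mfhas1 and Eri1, neighbours on opposite strands, were the called pair. Overlapping gene models are argued against by the 91601 bases between them, and depth by an edgeR adjusted p of at most 0.005655 for both with oocytes thinned to the same total. A candidate explanation is a difference local to this part of chromosome 8, such as inserted DNA or a stretch from another parental strain, neither of which the labels name: 0.0257% of pairs of tested genes lie as near. The closeness was seen before it was tested, and a response of both genes to the loss of Drp1 stays open, untested. The order of library preparation or sequencing is not given by the labels. If the index numbers follow it, it cannot be told apart from the label, since those of the labels do not overlap. Tube 29 of mouse 5, labelled Drp1_WT, held 20.8 CPM of Mfhas1 and 83.7 CPM of Eri1, within the range of the Drp1_KO label. Its Chrdl1 (4.95 CPM), Nif3l1 (42 CPM), Gulo (21.4 CPM) and Mctp1 (17.9 CPM) lie outside that range on the side of the Drp1_WT label. Its Trip10 (17.6 CPM), Plek (11.3 CPM), Dpp9 (3.03 CPM) and Dnm1l (234 CPM) lie within it, and its Dip2c (7.83 CPM) lies below all others of the Drp1_WT label. These genes except Dnm1l were picked by p in a fit that counted tube 29 as Drp1_WT, so their side is partly built in. The label of tube 29 stays open, untested. Without tube 29 edgeR still calls Mfhas1 and Eri1 (log2 3.50 and 1.14).

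Dnm1l lay at 116 to 156 CPM in WT tubes 11 to 15. An exchange with libraries labelled Drp1_KO is argued against, since 3 of those reach the level of the other 13 labelled Drp1_WT, fewer than 5 partners. Poor libraries are argued against by their detected genes, at least 13766 against a lowest value of 13508 in the others. In Mfhas1 and Eri1 these 5 libraries were unlike those labelled Drp1_KO. Mfhas1 reached at most 3.88 CPM and Eri1 at most 61.7 CPM, below every library labelled Drp1_KO (at least 19.4 and 72.4 CPM). Without these 5 libraries edgeR still calls both genes (adjusted p 0.0107 and 0.0345). Since a difference local to chromosome 8 stays possible, both genes may not report the state of Dnm1l. Wrongly labelled oocytes that lack Drp1 thus stay open. Oocytes from another source stay open, and no biological explanation was tested.

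Fewer detected genes under the Drp1_KO label may reflect several sources. Depth is argued against by an exact permutation p of 0.01587 with oocytes thinned to the same total, the smallest that the splits allow, and tube 10 as the whole source by an exact permutation p of 0.04762 without it, where the difference is -283 in place of -417 genes. A difference in library preparation or sequencing order is not excluded, since the labels do not give that order. If the index numbers follow it, it cannot be told apart from the label, since they end at 59 for Drp1_WT and start at 60 for Drp1_KO. The same holds for every comparison of the labels here, of genes and lists included. An effect of losing Drp1 stays open, untested.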
